A study of Arabidopsis thaliana with 12 samples.

How the data were processed

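The series holds 12 RNA-seq libraries of Arabidopsis thaliana, in 4 groups of 3. Wild type (WT) and psp1 plants, the latter mutated in phosphoserine phosphatase, were each divided into the aerial part and the roots. Per the labels' protocols, the plants grew upright on agar plates of diluted Murashige and Skoog medium after stratification at 4 °C, with 16 h of light and 8 h of dark per day. Both organs were collected when the night ended, and the replicates were independent biological samples. Total RNA was enriched for polyadenylated RNA and sequenced as single reads of 75 nucleotides on a SOLiD 5500XL instrument.

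Per the labels' protocols, the authors assigned reads to the TAIR10 transcriptome with kallisto 0.43.0, a program that matches reads to transcripts by their short words without placing them on the genome, with a fragment length of 200 bases and an SD of 30 set by hand. They then worked in R 3.3.2 with edgeR in its classic mode at a 1% level, and tested functional terms with topGO; those term tests were not used here. The deposited table of each library gives estimated counts per target, which need not be whole numbers because kallisto divides a read that matches several targets among them. Between 3.62% and 6.18% of the counts of a library were not whole, at a tolerance of 0.001. The deposited tables also give TPM, which the authors' program scales by target length and by the library's sum; TPM was not tested. Each table lists 27416 targets, 1 per locus, and 99.99% of target lengths were multiples of 3, so the targets hold coding sequence and a length is a coding length. Reads that match untranslated regions alone could not add to these counts. The effective lengths of long targets lay 199 bases below their lengths, the value that the stated fragment length gives. For a single read protocol without a stated strand rule, reads of overlapping genes on opposite strands cannot be told apart.

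Estimated counts were rounded to whole numbers. Gene names and coordinates came from the TAIR10.1 assembly and its annotation, joined by locus tag; 26719 loci (97.46%) matched, and GC content was known for 97.42%. Coordinates are therefore those of TAIR10.1, while the authors' targets carry the TAIR10 name. The main test of each comparison followed the mode and level in the labels: edgeR 4.0.16 in R 4.3.3, with TMM factors, a dispersion estimated without a design, the exact test between the groups, Benjamini-Hochberg adjustment and an adjusted p under 0.01 for a call. Each comparison of genotypes was fitted on the 6 libraries of its tissue, and each comparison of tissues on the 6 libraries of its genotype. Genes with too few counts were removed by the default filter of edgeR. The standard error of a log2 fold change came from the spread of the 3 libraries in each group on log2 CPM with a prior count of 2. The fold change itself came from the test. Where a group has few counts the prior narrows the spread, so the SE then understates the error. Printed CPM are relative to the library total. The difference of the psp1 effect between tissues was tested as an interaction in the edgeR quasi-likelihood model over all 12 libraries.

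Before the data were examined, 24 gene lists were fixed, with 418 places and 409 different loci. They cover serine synthesis, sulfur, glucosinolates, amino acids, mineral nutrition, defence, metabolism, the clock, and markers of leaf, root, flower and seed. One member of the aliphatic glucosinolate list, AOP2, was not analysed here. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists, with an adjusted p under 0.05 for a call; camera with an estimated correlation was the alternative. Fry, which asks whether the members of a list move on balance one way without comparing them with other genes, was the additional test. The genes named in the text followed a rule that was also fixed then. It took all genes of the phosphorylated serine pathway. It took the 5 largest rises and the 5 largest falls per tissue among called genes whose psp1 libraries all lay on one side of WT and whose higher group had a mean of at least 50 counts. It took up to 4 called members with the smallest p of each sulfur list and up to 2 of each other list. It also took the 3 genes with the smallest p in each direction of the interaction. Genes outside the rule are said to be.

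The test code was tested on simulated counts drawn from the real means and totals. In the simulated aerial comparison of 15928 genes, the exact test recovered 46% of 100 genes changed 2-fold and 92% of 100 genes changed 4-fold, and 7 calls (4.8%) were false. In roots, with 17793 genes, it recovered 52% and 90%, and 7 calls (4.7%) were false. The quasi-likelihood test recovered 36% and 85% in the aerial part, with 2 false calls (1.6%). When each genotype was simulated with its own spread, the exact test recovered 56% and 93% in the aerial part with 7 false calls (4.5%). The quasi-likelihood test then recovered 44% and 86% with 0 false calls. The false share of the exact test thus lay above the 1% level in both aerial simulations. In roots it did so with a common spread and not with a spread per genotype (0.7%). The simulated interaction recovered 84% of 200 genes changed 4-fold, with 2 false calls among 18759 genes. In the list simulation, camera called 5 of 5 lists of 20 genes that were shifted by 0.8 on the log2 scale and 0 of 5 unshifted lists. The simulated genes were drawn independently of each other, so this could not check the preset correlation. In all these simulations, changes were given only to genes with a mean of at least 20 counts. For the interaction, at least 20 counts had to be expected in each tissue. Recovery at lower counts was not measured.

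Library totals ran from 3627193 to 9590308 estimated counts. For a gene without counts in a group, the fold is a lower bound computed against 3 counts over the group, and for a gene with 1 to 3 counts the ratio has a 95% exact interval. Such bounds and intervals cover counting error only. Genes whose coding sequence shared at least 100 aligned bases at 90% identity with another locus were marked as near copies, because kallisto may divide their reads.

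The alternatives fixed before the data were examined were the quasi-likelihood test, DESeq2 1.42.0, RLE factors, library totals without factors, no filter and a filter of 50 counts in 3 libraries, a dispersion from all 12 libraries, removal of organelle loci, other thresholds, a replicate block, and leaving out each library in turn. Thinning all libraries to the smallest, and comparing psp1 aerial 1 alone with WT, were added after the data were seen, as were 14 gene families named by their annotated products. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.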

Results

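The data are estimated read counts per gene for the aerial part and the roots of Arabidopsis seedlings, from wild type (WT) and from the psp1 mutant of phosphoserine phosphatase. Each of the 4 groups had 3 libraries. Total counts were 8958217, 8317869 and 7302386 in WT aerial libraries 1 to 3 and 7445059, 9122881 and 9590308 in WT root libraries 1 to 3. The libraries labelled psp1 were shallower, with 5815906, 3757545 and 3627193 counts in the aerial part and 5873935, 4920392 and 4191768 in roots. Depth therefore separated the genotypes completely in both tissues. Values below are CPM as mean ± SD, or log2 fold changes of the libraries labelled psp1 over WT ± SE, with n = 3 per group throughout. Unless another test is named, adjusted p-values come from the edgeR exact test, or from camera for gene lists.

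The title of the series asks whether a defect in the phosphorylated pathway of serine synthesis disturbs sulfur assimilation. PSP1 (AT1G18640; TAIR10.1 chromosome 1, 6416169 to 6418693, minus strand), the phosphoserine phosphatase of the last step of that pathway, is the mutated gene. Its estimated counts were 661, 535 and 368 in WT aerial libraries 1 to 3, against 2331, 1144 and 883 in the aerial libraries labelled psp1. In roots they were 1241, 1441 and 1352 in WT and 667, 599 and 608 in the libraries labelled psp1. In CPM, PSP1 stood at 62.8 ± 11.8 in WT and 316 ± 79.3 in the psp1-labelled aerial libraries, a rise of 2.29 ± 0.26 on the log2 scale or 4.88-fold (adjusted p = 1.6e-22). In roots it stood at 155 ± 13.1 and 127 ± 16.3 CPM, a difference of -0.40 ± 0.13 that was not called (adjusted p = 0.0275). Without psp1 root library 3 that difference was -0.52 and was called (adjusted p = 0.00189, the lowest of a range that reached 0.161). The mutated gene thus stood above WT in the aerial libraries labelled psp1, so the genotype is named as labelled and every direction is that of the labels. The counts cover coding sequence and do not show whether the transcripts are intact.

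**Figure D1:**
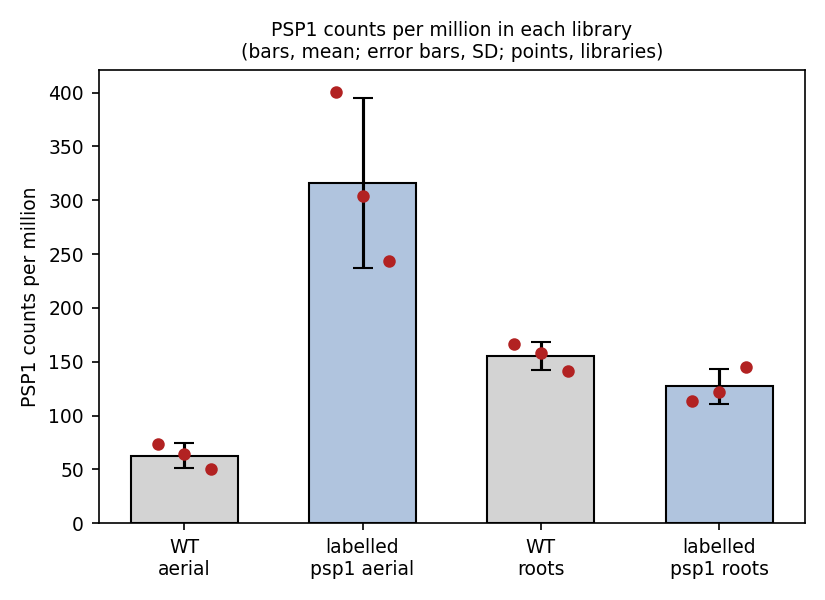
PSP1 counts as CPM of the library total (vertical axis) in the 4 groups; points are the 12 libraries, bars the group means and error bars the SD over 3 libraries. The aerial libraries labelled psp1 lie between 243 and 401 CPM, all above the WT aerial libraries.

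Of the other enzymes of the phosphorylated serine pathway, 1 had a called change. PSAT1, a phosphoserine aminotransferase, rose in psp1-labelled roots from 99.9 to 191 CPM (0.83 ± 0.09, adjusted p = 3.38e-08). The dehydrogenase PGDH1 differed by -0.12 in the aerial part and 0.10 in roots, and PGDH2 by 0.82 and 0.39 (adjusted p = 0.0224 and 0.0416). PGDH3 differed by -0.15 in the aerial part, and PSAT2 by -0.42 and 0.18. None of these was called in the main test, and PGDH2 is uncertain because AT1G17744 is identical to it over 425 bases. Over the alternatives in the aerial part PGDH1 ran from -0.75 to 0.11, PGDH3 from -0.65 to 0.05 and PSAT2 from -0.99 to 0.25. For PGDH2 the adjusted p ran from 0.00217 to 0.286 over the alternatives in the aerial part and from 0.00495 to 0.256 in roots. As a list, the pathway had 1 called rise (PSP1) among 6 tested members in the aerial part (2 rises adjusted over the list alone, list adjusted p = 0.0599). The list was called up in 5 of 10 alternatives, without WT aerial 1 (adjusted p = 0.0496), WT aerial 2 (0.028) or psp1 aerial 1 (0.0449), with a replicate block (0.0284) and at equal depth (0.0462). With an estimated correlation it was not (0.22). In roots it had 1 (PSAT1) among 5 (1 adjusted over the list alone, list adjusted p = 0.238).

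In the aerial part, genes of the sulfur deficiency response rose in the libraries labelled psp1. Of the aliphatic glucosinolate genes 7 of 21 fell, a list call lost with an estimated correlation (adjusted p = 0.061), and the quasi-likelihood test called 0 of them. SDI1 (AT5G48850; TAIR10.1 chromosome 5, 19805437 to 19807853), a repressor of glucosinolate synthesis that is induced by sulfur shortage, rose 21.7-fold, from 0.783 to 17.79 CPM (4.44 ± 0.16, adjusted p = 1.91e-27). The APS reductases, which reduce activated sulfate, rose from 43.4 to 199 CPM for APR3 (2.16 ± 0.10, adjusted p = 2.72e-37) and from 14.2 to 69.7 CPM for APR1 (2.25 ± 0.25, adjusted p = 1.52e-18). LURP1, a gene needed for resistance to downy mildew, rose from 7.79 to 51.1 CPM (2.67 ± 0.08, adjusted p = 5.48e-34). BCAT4 (AT3G19710; TAIR10.1 chromosome 3, 6846969 to 6849582), which starts the chain elongation of methionine for aliphatic glucosinolates, fell from 43.4 to 20.4 CPM (-1.14 ± 0.23, adjusted p = 6.92e-05).

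Of 10 tested members of the sulfur deficiency list, 7 rose and 1 fell (8 and 1 adjusted over the list alone). Its median was 2.12 (list adjusted p = 4.29e-12, and 0.0325 with an estimated correlation). This was the only list of the aerial part called with an estimated correlation as well. Besides SDI1, APR1 and APR3, the list held SDI2 (2.38 ± 0.12, adjusted p = 1.01e-21) and APR2 (0.83 ± 0.08, from 272 to 499 CPM, adjusted p = 3.04e-06). SDI2 shares 105 bases at 91.4% identity with AT1G49940 and is uncertain to that extent, in roots too. SULTR4;2, which releases sulfate from the vacuole, rose by 2.08 ± 0.45 (adjusted p = 0.000686, but 0.0405 without WT aerial 2 and 0.0353 without WT aerial 3). The member that fell was SULTR2;1 (AT5G10180; TAIR10.1 chromosome 5, 3193017 to 3197136), a vascular sulfate transporter, from 129 to 70.3 CPM (-0.92 ± 0.06, adjusted p = 2.87e-07). The 3 APS reductases were the called members among 22 of sulfate reduction and cysteine synthesis (3 rises adjusted over the list alone, median 0.11). That list was called at an adjusted p of 0.000358 and lost with an estimated correlation (adjusted p = 0.22) and with psp1 aerial 1 alone (0.149). Among 9 sulfate transporters 1 rose and 1 fell (2 and 1 adjusted over the list alone). Their list was not called (adjusted p = 0.82). Its median of -0.06 and its test pointed down while its mean was 0.22. MSRB5, a methionine sulfoxide reductase, rose from 6.51 to 53.4 CPM (3.00 ± 0.37, adjusted p = 1.38e-23).

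**Figure D2:**
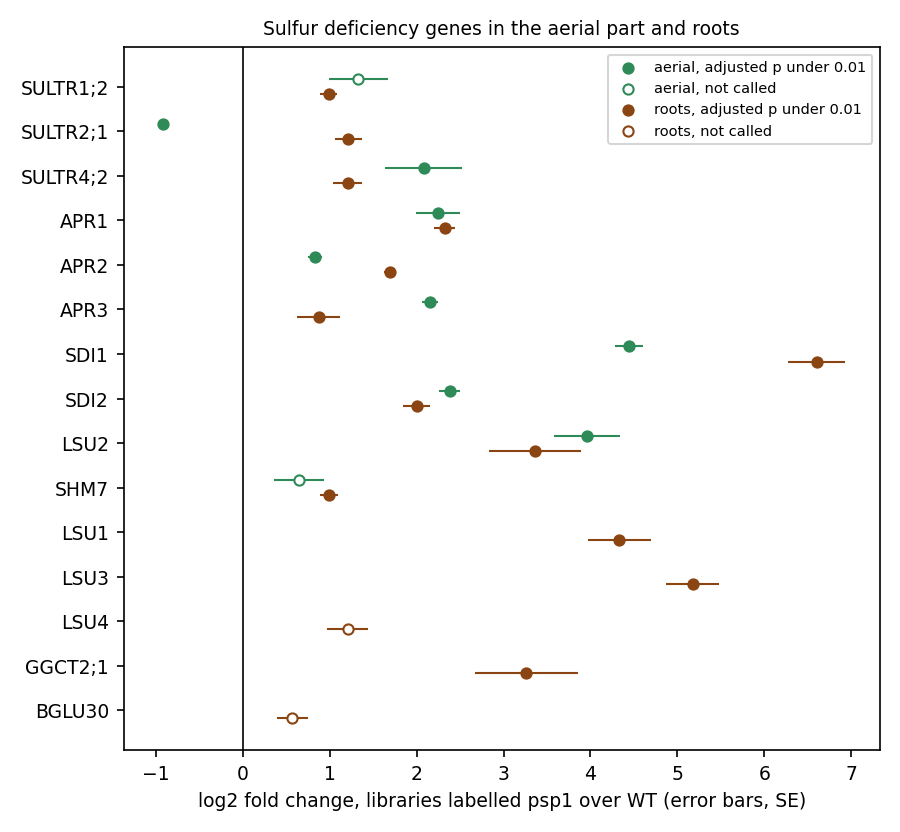
Log2 fold change of the libraries labelled psp1 over WT (horizontal axis) for each tested member of the sulfur deficiency list, in the aerial part (green) and roots (brown); error bars are SE with 3 libraries per group, and filled points have an adjusted p under 0.01. SDI1 lies at 4.44 in the aerial part and 6.60 in roots, and SULTR2;1 at -0.92 and 1.22.

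Among the aliphatic glucosinolate genes of the aerial part 7 of 21 fell and none rose (9 and 0 adjusted over the list alone). Their median was -0.71 (list adjusted p = 9.07e-10, and 0.061 with an estimated correlation). An unadjusted p under 0.05 was reached by 13 members, while the quasi-likelihood test called 0 and DESeq2 7. CYP83A1, which oxidises aldoximes in this route, fell from 98.5 to 51.6 CPM (-0.98 ± 0.18, adjusted p = 2.94e-05). IPMI1, a subunit of the isopropylmalate isomerase, fell by 2.32 ± 0.95 (adjusted p = 0.000705, but 0.0307 to 0.0372 without WT aerial 1, 2 or 3). Its log2 fold change was -3.34 without psp1 aerial 1 and -1.50 with that library alone. In the methionine and methyl cycle, 2 of 16 fell (4 adjusted over the list alone). Its median was -0.33 (list adjusted p = 0.000358, and 0.22 with an estimated correlation). These were MTHFR1, a folate reductase, from 288 to 189 CPM (-0.65 ± 0.09, adjusted p = 0.00105) and the methionine synthase MS2 from 93.9 to 57.7 CPM (-0.74 ± 0.16, adjusted p = 0.00173). Left-out libraries ended both calls, at 0.063 and 0.0601 without WT aerial 1, 0.0394 and 0.0216 without WT aerial 2, and for MS2 0.0322 without WT aerial 3. APK2, an APS kinase that supplies activated sulfate, was the 1 gene that fell among 14 of the indolic and shared core list (2 adjusted over the list alone). It stood at -1.26 ± 0.39 (adjusted p = 0.00145, but 0.0569 without WT aerial 3 and 0.0173 without psp1 aerial 2). The indolic list was not called (adjusted p = 0.726, test down, median 0.02). Nor was tryptophan synthesis, with 0 of 11 members called (0 adjusted over the list alone, median 0.00, list adjusted p = 0.838).

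**Figure D3:**
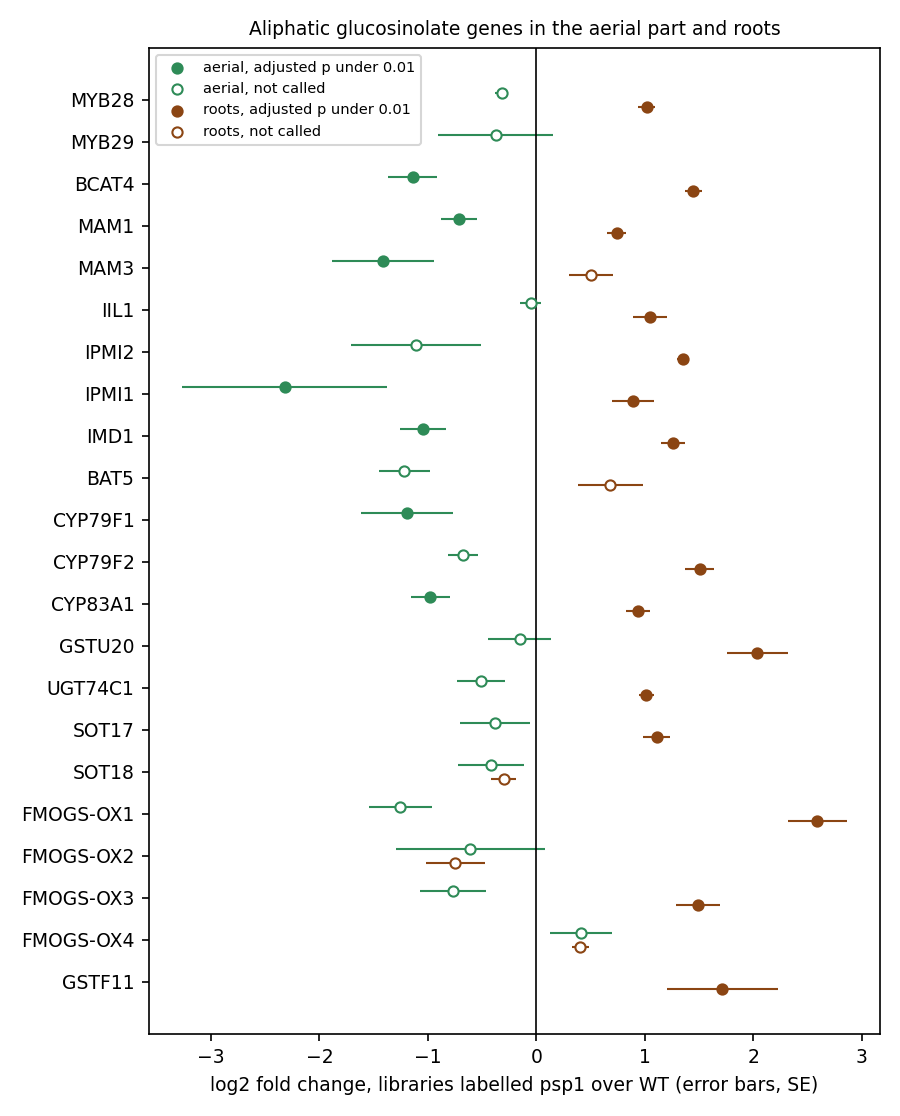
Log2 fold change of the libraries labelled psp1 over WT (horizontal axis) for each tested member of the aliphatic glucosinolate list, in the aerial part (green) and roots (brown); error bars are SE with 3 libraries per group, and filled points have an adjusted p under 0.01. The list medians are -0.71 in the aerial part and 1.03 in roots.

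Phosphate starvation genes rose in the psp1-labelled aerial part, 5 of 11 (7 adjusted over the list alone). Their median was 1.21 (list adjusted p = 9.54e-10, and 0.061 with an estimated correlation). SPX1, a sensor of inositol phosphates that restrains the phosphate response, rose by 3.08 ± 0.30 (adjusted p = 1.8e-09) and the acid phosphatase PAP17 by 2.26 ± 0.19 (adjusted p = 7.57e-12). In salicylic acid defence 4 of 13 rose (4 adjusted over the list alone). Its median was 0.53 (list adjusted p = 1.61e-08, and 0.0978 with an estimated correlation). Beside LURP1 these included the defence regulator ACD6, from 57.6 to 281 CPM (2.25 ± 0.08, adjusted p = 2.98e-45), and the transcription factor WRKY70 (1.62 ± 0.09, adjusted p = 2.43e-18). The heat shock list was not called (1 of 7 rose, 1 adjusted over the list alone, median 0.37, adjusted p = 0.0689). Its riser was HSP70 (1.95 ± 0.36, adjusted p = 4.83e-05, but 0.0114 without WT aerial 1). In the jasmonate list 1 of 11 fell (1 adjusted over the list alone). It was not called (list adjusted p = 0.736, test down, median 0.02, mean -0.60). Its falling member was TAT3, a tyrosine aminotransferase induced by jasmonate, with 73 counts over the WT and 0 over the psp1-labelled libraries, at least 13.1-fold lower (adjusted p = 2.95e-07). Nitrogen assimilation had 0 of 18 called (1 rise adjusted over the list alone, test up, median -0.02 or 0.02 with library totals, adjusted p = 0.746). Iron deficiency had 0 of 8 (0 adjusted over the list alone, median 0.23, adjusted p = 0.518).

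Photosynthesis genes, which also mark leaf tissue, had 2 falls and no rise among 27 (4 and 0 adjusted over the list alone). Their median was -0.25 (list adjusted p = 6.77e-07, and 0.296 with an estimated correlation). PSBS, which dissipates excess light energy, fell from 832 to 506 CPM (-0.76 ± 0.20, adjusted p = 0.00225, but 0.0787 without WT aerial 1 and 0.0535 without WT aerial 2). LHCB3, an antenna protein, fell from 2360 to 1680 CPM (-0.54 ± 0.06, adjusted p = 0.00876). That call was lost without any 1 of WT aerial 1, 2 and 3 or psp1 aerial 2 and 3 (adjusted p = 0.19, 0.0569, 0.0771, 0.0326 and 0.013). Photorespiration, the other main source of serine, had 0 of 18 members called (0 adjusted over the list alone, median -0.15). Its list test pointed down at an adjusted p of 0.0364, lost with an estimated correlation (adjusted p = 0.423), with a replicate block (0.0607), without WT aerial 2 (0.0717) and without psp1 aerial 1 (0.3). Cell division had 1 fall among 21 (1 adjusted over the list alone). Its median was -0.27 (list adjusted p = 0.0319, and 0.217 with an estimated correlation). That list was not called without WT aerial 1 (0.0528), WT aerial 2 (0.143) or psp1 aerial 2 (0.115), at equal depth (0.097) or with psp1 aerial 1 alone (0.256). Its falling member was the cyclin CYCB1;3, from 2.17 to 0.229 CPM (-2.87 ± 0.57, adjusted p = 0.00368, but 0.0187 without WT aerial 3, 0.0182 without psp1 aerial 2 and 0.0125 without psp1 aerial 3). It stood at -6.82 without psp1 aerial 1 and -1.73 with that library alone, where it was not called (adjusted p = 0.14), so the size of its fall is uncertain. Carbon starvation had 1 fall among 15, MCCA of leucine breakdown (-0.52 ± 0.06, adjusted p = 0.00938, but between 0.0267 and 0.156 without WT aerial 1, 2 or 3 or psp1 aerial 2 or 3). The list had 3 falls adjusted over the list alone and a median of -0.18. It was called at an adjusted p of 0.0301, and lost with an estimated correlation (adjusted p = 0.217), without psp1 aerial 2 (0.0887) or psp1 aerial 3 (0.136), and with psp1 aerial 1 alone (0.349). Flavonoid synthesis (0 of 10, median -0.20, adjusted p = 0.357), the clock (0 of 9, median -0.15, adjusted p = 0.34) and Casparian strip genes (0 of 7, median -0.30, adjusted p = 0.429) were not called. All 3 had 0 members called adjusted over the list alone. Among the lists without a called member of the aerial part, an unadjusted p under 0.05 was reached by 6 photorespiration, 4 nitrogen, 2 flavonoid and 2 clock genes. It was reached by 1 gene each of tryptophan synthesis, iron deficiency and Casparian strip. In these lists DESeq2 called 1 photorespiration and 1 clock gene, and the quasi-likelihood test 0 genes. Of the root hair list, PYK10 alone was tested in the aerial part (-0.15 ± 0.09, adjusted p = 0.684), so no list test was made there.

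Among the largest single changes of the aerial part, AT1G33120, a ribosomal protein L6 gene, rose from 53.5 to 364 CPM (2.73 ± 0.40, adjusted p = 3.63e-17). It shares 99.1% identity with its neighbour PGY2, so its reads could be divided between both and its value is uncertain. THA1, a threonine aldolase that makes glycine, rose by 1.33 ± 0.28 (adjusted p = 1.35e-06). The largest falls by the rule for named genes (a mean of at least 50 counts in the higher group, and every psp1-labelled library below every WT one) were IPMI1, the repeat protein gene AT3G62540 (-2.72 ± 0.99, adjusted p = 0.00249) and the receptor kinase gene AT3G46370 (-2.48 ± 0.68, adjusted p = 0.000944). AT1G72645, which has no known product (-2.14 ± 0.78, adjusted p = 0.00393), and AT1G32410 of the VPS55 family (-1.94 ± 0.24, adjusted p = 0.000343) followed. AT3G62540 has a near copy, AT5G14820, at 99.7% identity and is uncertain too. The acyltransferase gene AT2G39980 fell by 0.67 ± 0.10 (adjusted p = 0.00689). Left-out libraries ended the calls of these last 5 genes. The falls of AT3G62540, AT3G46370 and AT1G72645 also depended on psp1 aerial 1, at -4.17, -3.58 and -3.69 without it and -1.72, -1.64 and -1.13 with it as the sole psp1-labelled library. The adjusted p was highest without WT aerial 3 for AT3G62540 (0.0886) and without WT aerial 1 for AT3G46370 (0.0764), AT1G72645 (0.0999), AT1G32410 (0.0364) and AT2G39980 (0.155).

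The psp1-labelled aerial libraries varied more among themselves than the WT ones, with a biological coefficient of variation of 23.9% against 11.2%. Across all 15928 genes tested in the aerial part, 243 rose and 144 fell, 387 in all. The edgeR quasi-likelihood test called 31 (28 and 3), and of the 33 named aerial calls it lost 19. These include IPMI1, BCAT4, CYP83A1, SULTR4;2, MS2 and LHCB3 (adjusted p = 0.0805, 0.0228, 0.0186, 0.0481, 0.0421 and 0.0373, in a range over all alternatives from 6.72e-08 to 0.19). PSP1, SDI1, MSRB5, AT1G33120, LURP1, APR3, APR1, SDI2, PAP17, ACD6 and WRKY70 were called under every alternative run. Without 1 library the count was 112, 140 and 128 for WT aerial 1, 2 and 3, and 710, 372 and 555 for psp1 aerial 1, 2 and 3.

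In roots, the sulfur, phosphate and iron starvation genes and the aliphatic glucosinolate genes rose in the libraries labelled psp1, and carbon starvation genes fell. SDI1 rose 97-fold, from 0.471 to 50.1 CPM (6.60 ± 0.33, adjusted p = 8.61e-75). SPX1 rose by 4.07 ± 0.18 (adjusted p = 9.84e-84), and BCAT4 rose from 138 to 407 CPM (1.45 ± 0.08, adjusted p = 5.21e-25). NAS2, a nicotianamine synthase of iron transport, rose by 3.52 ± 0.21 (adjusted p = 2.23e-52). DIN10, a raffinose synthase induced by darkness and sugar shortage, fell from 1120 to 346 CPM (-1.81 ± 0.22, adjusted p = 1.03e-20).

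Of 15 tested members of the sulfur deficiency list, 13 rose in psp1-labelled roots and none fell (14 and 0 adjusted over the list alone). Their median was 1.69 (list adjusted p = 1.36e-14, and 0.0113 with an estimated correlation). APR1 rose by 2.33 ± 0.12, APR2 by 1.69 ± 0.06, SDI2 by 2.00 ± 0.15 and APR3 by 0.88 ± 0.25, with an adjusted p of 4.29e-05 for APR3. Among 10 sulfate transporters 6 rose and none fell (6 and 0 adjusted over the list alone). Their median was 1.00 (list adjusted p = 3.24e-05, and 0.0593 with an estimated correlation). SULTR1;3, which loads sulfate into the phloem, rose from 0.36 to 18 CPM (5.51 ± 0.40, adjusted p = 2.69e-30) and SULTR2;1 from 63.5 to 159 CPM (1.22 ± 0.16, adjusted p = 5.11e-13). Over the alternatives the log2 fold change of SULTR1;3 ran from 5.05 to 7.3, and it stayed called. The uptake transporter SULTR1;2 rose by 0.99 ± 0.09 and SULTR4;2 by 1.21 ± 0.17. In sulfate reduction and cysteine synthesis 5 of 22 rose and 1 fell (6 and 1 adjusted over the list alone). Its median was 0.21 (list adjusted p = 0.0128, and 0.255 with an estimated correlation). SERAT3;2, a serine acetyltransferase, rose by 2.93 ± 0.46.

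Aliphatic glucosinolate genes rose in 15 of 20 cases and none fell (18 and 0 adjusted over the list alone). Their median was 1.03 (list adjusted p = 3.97e-12, and 0.013 with an estimated correlation). CYP79F2, the entry enzyme for long-chain aliphatic glucosinolates, rose by 1.51 ± 0.13 (adjusted p = 1e-21). It shares 92.0% identity with CYP79F1 and is uncertain to that extent. CYP83A1 rose by 0.94 ± 0.11 and IPMI1 by 0.89 ± 0.19, the latter not called without WT roots 2 (adjusted p = 0.0106) or psp1 roots 1 (0.0124). The indolic and shared core list went both ways, with 5 rises and 2 falls among 15 (5 and 4 adjusted over the list alone, median 0.22, list adjusted p = 0.338). CYP79B3, the entry enzyme of the indolic branch, fell from 271 to 107 CPM (-1.45 ± 0.04, adjusted p = 1.94e-26), while the peptidase GGP1 rose by 1.01 ± 0.15. In the methionine and methyl cycle 6 of 16 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.20, list adjusted p = 0.106). MS2 rose from 339 to 689 CPM (0.92 ± 0.07, adjusted p = 1.44e-10) and SAHH2, a homocysteine-forming hydrolase, by 0.94 ± 0.13. Tryptophan synthesis had 1 rise among 11 (1 adjusted over the list alone, median 0.32, list adjusted p = 0.0953), PAT1 of the anthranilate step (0.78 ± 0.07).

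Phosphate starvation genes rose in 17 of 19 cases and none fell (18 and 0 adjusted over the list alone). Their median was 2.33 (list adjusted p = 1.56e-17, and 0.0113 with an estimated correlation). The phosphate transporter gene PHT1;4 (2.62 ± 0.20, adjusted p = 1.85e-48) and PAP17 (2.39 ± 0.36) were among them. Iron deficiency genes rose in 13 of 19 cases and none fell (15 and 1 adjusted over the list alone). Their median was 1.40 (list adjusted p = 8.83e-10, and 0.0152 with an estimated correlation). Among them was CYP82C4 of coumarin synthesis (2.76 ± 0.28), which is uncertain because CYP82C2 shares 92.8% of its sequence. In nitrogen assimilation 12 of 20 rose and 3 fell (13 and 3 adjusted over the list alone). Its median was 0.69 (list adjusted p = 1.19e-06, and 0.13 with an estimated correlation). GLN1;2 (AT1G66200; TAIR10.1 chromosome 1, 24655115 to 24657703), a cytosolic glutamine synthetase, rose from 353 to 2040 CPM (2.42 ± 0.23, adjusted p = 2.26e-35) and the nitrate transporter NRT1.1 by 1.67 ± 0.11 (adjusted p = 1.51e-29). Carbon starvation genes fell in 13 of 16 cases and none rose (13 falls and 1 rise adjusted over the list alone). Their median was -0.88 (list adjusted p = 4.42e-09, and 0.0152 with an estimated correlation). They included TPS11 of the trehalose phosphate synthase family (223 to 120 CPM, adjusted p = 1.29e-12) and MCCA (-1.01).

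Salicylic acid defence genes rose in 11 of 16 cases and 1 fell (11 and 1 adjusted over the list alone). Their median was 1.16 (list adjusted p = 1.89e-05, and 0.0478 with an estimated correlation). FMO1 of systemic resistance stood at 2.98 ± 0.31 (adjusted p = 1.81e-28) and WRKY70 at 1.46 ± 0.14. The jasmonate list had 3 rises and 2 falls among 8 (3 and 2 adjusted over the list alone, median 0.65, list adjusted p = 0.216). The repressor gene JAZ1 rose by 1.70 ± 0.13 and the storage protein gene VSP2 fell by 2.00 ± 0.26 (adjusted p = 1.56e-21). Flavonoid genes rose in 4 of 8 cases (4 adjusted over the list alone). Their median was 0.83 (list adjusted p = 0.00121, and 0.255 with an estimated correlation). Flavonol synthase FLS1 rose by 2.72 ± 0.35 and F3H of the same route by 1.31 ± 0.17. Heat shock genes were not called as a list (2 of 8 rose, 2 adjusted over the list alone, adjusted p = 0.744, test up, median -0.26, mean 0.01). HSP90.1 rose by 0.83 ± 0.18 and HSP70 by 0.72 ± 0.14. The clock list had 1 fall among 12 (1 adjusted over the list alone, median -0.16, list adjusted p = 0.157), RVE1 (-1.13 ± 0.13), a morning-phased regulator of auxin levels.

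Photosynthesis genes fell in 10 of 27 cases and none rose (10 and 0 adjusted over the list alone). Their median was -0.48 (list adjusted p = 1.12e-05, and 0.226 with an estimated correlation). LHCB3 fell from 127 to 48.4 CPM (-1.51 ± 0.14, adjusted p = 1.18e-19), and the photosystem subunit gene PSAN stood at -1.46 ± 0.20. Photorespiration had 1 rise and 4 falls among 17 (1 and 4 adjusted over the list alone, median -0.15, list adjusted p = 0.106, but called without psp1 roots 3 at 0.0272). Glycerate kinase GLYK stood at -1.11 ± 0.05 (adjusted p = 2.12e-14) and SHM1, a hydroxymethyltransferase that forms serine, at -0.86 ± 0.20. Root hair and epidermis genes went both ways, 3 up and 3 down among 10 (3 and 3 adjusted over the list alone, median 0.21, list adjusted p = 0.98). The cell wall gene LRX1 rose by 2.24 ± 0.28 and the aquaporin gene TIP2;3 fell by 1.07 ± 0.15. Summed over that list, expression was 5457 ± 417 CPM in WT roots and 3879 ± 588 CPM in psp1-labelled roots. PYK10 alone made up most of the sum in WT roots, so the sum mainly follows that gene and not the list. Casparian strip and suberin genes rose in 5 of 19 cases (6 adjusted over the list alone). Their median was 0.18 (list adjusted p = 0.0288, and 0.226 with an estimated correlation or 0.0675 without WT roots 2). They included ASFT of suberin synthesis (0.78 ± 0.07) and the peroxidase gene PER64 (0.91 ± 0.15). Cell division had 1 rise and 4 falls among 26 (1 and 4 adjusted over the list alone, median -0.14, list adjusted p = 0.27). CDC20.1 fell by 0.79 ± 0.14, uncertain because CDC20.2 is a near copy at 97.5% identity. The kinesin gene HINKEL fell by 0.67 ± 0.19 (adjusted p = 0.00209, but 0.032 without WT roots 1 and 0.0179 without WT roots 3). The flower and seed lists had no member with enough counts for a test in either tissue, and their summed expression stayed at or under 3.35 and 0.64 CPM in each group.

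The largest single changes of roots included NDB4, an external NADH dehydrogenase of mitochondria, with 3 counts over the WT and 327 over the psp1-labelled libraries, a ratio of 190 with a 95% interval of 64.5 to 927 (adjusted p = 4.67e-46). TIF3C2, a copy of translation initiation factor subunit eIF3c, rose by 5.74 ± 0.27 (adjusted p = 3.09e-30) and the carbonic anhydrase gene BCA3 by 5.54 ± 0.29 (adjusted p = 1.68e-41). The resistance gene AT1G59124 had 217 counts over WT roots and 0 over psp1-labelled roots, at least 41.4-fold lower. It is identical to AT1G58807 over the aligned stretch and so uncertain. The peroxidase gene AT2G39040 was at least 32.1-fold lower (168 counts against 0). The arabinogalactan protein gene AGP30 (-5.67 ± 0.44), the MADS-box gene AGL17 (-4.57 ± 0.55) and the lectin gene AT5G35940 (-4.03 ± 0.32) fell. TIF3C2 stood at 0.242 CPM in WT roots and AGP30 at 0.238 CPM in psp1-labelled roots. With so few counts their SE understate the error. On the log2 scale NDB4 stood at 7.25, and at 8.00 without WT roots 2, AGP30 at -6.83 without psp1 roots 1 and AGL17 at -6.15 without psp1 roots 2, all still called.

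Of 17793 genes tested in roots, 1552 rose and 1620 fell, 3172 in all, with 2232 under the quasi-likelihood test. Scaling by library totals alone gave a median of all genes of 0.122 on the log2 scale, against 0.011 in the main fit. It gave 2142 rises and 1182 falls, so the balance of directions depends on the scaling.

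**Figure D4:**
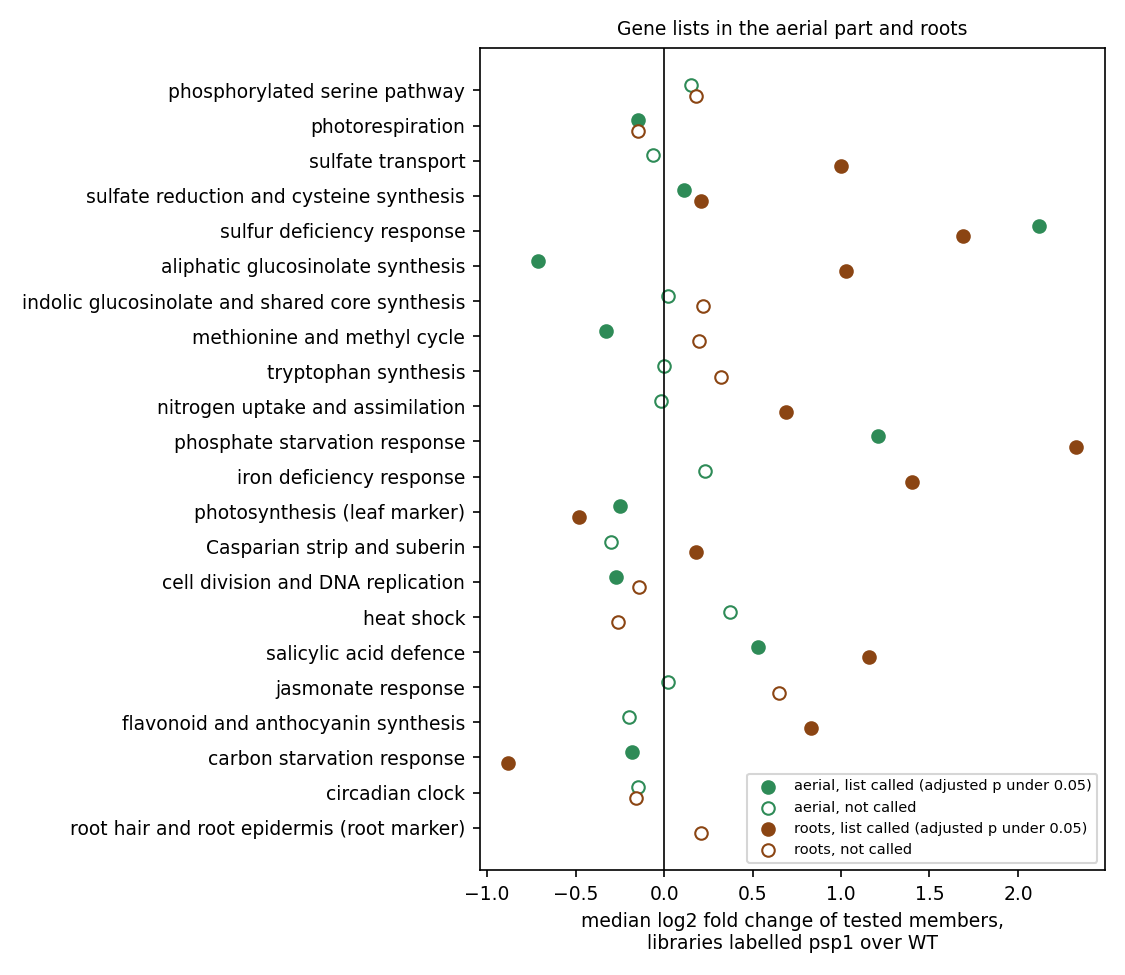
Median log2 fold change of the libraries labelled psp1 over WT (horizontal axis) for each gene list in the aerial part (green) and roots (brown), over the members tested; filled points are lists called by camera at an adjusted p under 0.05. Aliphatic glucosinolate genes are called on opposite sides of 0, at -0.71 and 1.03, the aerial call being lost with an estimated correlation (adjusted p = 0.061).

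The interaction asked which psp1 effects differed between tissues. For aliphatic glucosinolate synthesis the difference (roots minus aerial part) had a median of 2.14 on the log2 scale. Of its 22 members 16 had a called difference, all towards roots (list adjusted p = 4.46e-21, and 0.00119 with an estimated correlation). BCAT4 differed by 2.69 (adjusted p = 9.18e-07), CYP83A1 by 2.01 (1.49e-05), IPMI1 by 3.25 (0.0018) and CYP79F2 by 2.26 (5.1e-05), all from the edgeR quasi-likelihood test. SULTR2;1, which fell in the aerial part and rose in roots, differed by 2.23 (adjusted p = 2.35e-06) and MS2 likewise by 1.75 (2.51e-05). The opposite held for PSP1, whose effect was lower in roots by -2.60 ± 0.31 (adjusted p = 9.64e-06), and for THA1 (AT1G08630; TAIR10.1 chromosome 1, 2743761 to 2747967), which rose in the aerial part and fell in roots from 19.3 to 1.3 CPM (-3.91 ± 0.52), with a difference of -5.11 (adjusted p = 3.77e-06). Without psp1 roots 1 THA1 stood at -4.74 in roots and differed by -6.07, and without psp1 aerial 1 IPMI1 differed by 4.36.

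Phosphate starvation (median difference 1.14, adjusted p = 1.11e-06, and 0.00322 with an estimated correlation) and iron deficiency (0.77, adjusted p = 0.00019, and 0.04 with an estimated correlation) were also called towards roots. Carbon starvation (-0.69, adjusted p = 7.4e-08, and 0.00322 with an estimated correlation) was called towards the aerial part. Nitrogen assimilation (0.82, adjusted p = 2.2e-06), the methionine cycle (0.63, 8.24e-06), sulfate transport (0.57, 0.0114), flavonoid synthesis (1.04, 0.00598) and photosynthesis (-0.14, 0.00598, and 0.0756 without psp1 aerial 3) were lost with an estimated correlation (adjusted p = 0.074, 0.0671, 0.0671, 0.15 and 0.324). The sulfur deficiency list was not called (adjusted p = 0.234, test up, median -0.27), but it was called towards roots at equal depth (adjusted p = 0.0371). Salicylic acid defence was not called (0.574). The same held for sulfate reduction (0.759), serine synthesis (0.343), photorespiration (0.574), the indolic list (0.0972), tryptophan (0.234), root hair (0.301), Casparian strip (0.0886), cell division (0.359), heat shock (0.137), jasmonate (0.0972) and the clock (0.355). Single left-out libraries brought calls for some of these: the indolic list without WT roots 2 (0.0415), root hair without psp1 roots 3 (0.029) and jasmonate without psp1 roots 2 (0.0319). Heat shock was called without WT aerial 2 (0.0481) or psp1 aerial 1 (0.0338). Casparian strip was called without WT aerial 2 (0.0481), WT roots 1 (0.0371), psp1 aerial 1 (0.0356) or psp1 roots 1 (0.0457). The smallest p-values towards roots belonged to EMB1030, an alanyl-tRNA synthetase gene that rose in roots from 15.8 to 110 CPM (2.69 ± 0.08, adjusted p = 1.5e-57), the glycerol-3-phosphate permease gene G3Pp1, from 30.8 to 279 CPM (3.07 ± 0.13, adjusted p = 8.61e-75), and AT2G39980 (2.65 ± 0.21 in roots). EMB1030 shares 108 bases at 96.3% identity with AT1G49930 and is uncertain to that extent. Towards the aerial part they belonged to CYP81D11, a cytochrome P450 gene induced by foreign compounds, which fell in roots from 213 to 40.3 CPM (-2.51 ± 0.19), with THA1 and PSP1.

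In total 315 of 18759 genes had a called difference, 153 towards roots and 162 towards the aerial part. RLE factors gave 143 and 234, and DESeq2 331 and 497. Without WT aerial 1, 2 or 3 the count was 170, 136 or 194.

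Calls in both tissues overlapped. Among 15071 genes tested in both, 72 rose in both, SDI1 and SPX1 among them, where independent lists would share 15.9 (Fisher's exact test p = 2.88e-29), and 50 fell in both, against 12.3 (p = 4.82e-19). Of the opposite kind, 12 rose in the aerial part and fell in roots (20.7 by chance), THA1 among them, and 13 fell in the aerial part and rose in roots (9.5 by chance), BCAT4 and SULTR2;1 among them. Across genes, which are not independent replicates, the log2 fold changes of both tissues had a Pearson r of 0.247 and a Spearman rho of 0.228. The overlapping calls shared no libraries between tissues, but the psp1-labelled libraries were the shallower ones in both. Fisher's exact test counts genes as independent units, so its p-values do not allow for genes that change together.

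Comparing roots with the aerial part within a genotype tested whether the libraries hold the tissue on their label. In WT, LHCB3 stood at 2360 CPM in the aerial part and 127 CPM in roots (-4.72 ± 0.09), and the Rubisco activase gene RCA at 20390 and 139 CPM (-7.70 ± 0.09). The Casparian strip gene PER64 (0.280 and 22.5 CPM, 5.73 ± 0.34) and PYK10, a beta-glucosidase gene (312 and 5208 CPM, 3.55 ± 0.10), stood higher in roots. RCA and PYK10 were chosen here from the marker lists after their values were seen. In the libraries labelled psp1 the log2 differences were -5.68 ± 0.12 for LHCB3, -7.62 ± 0.27 for RCA and 3.10 ± 0.13 for PYK10. The edgeR exact test called all of these. Of 18202 genes in WT 6114 were higher in roots and 5615 lower, and of 17344 in the libraries labelled psp1 4363 and 4252. With library totals alone the medians of all genes were 0.543 and 0.603, against 0.032 and 0.043 in the main fits. The counts were then 9109 and 3663 in WT and 7137 and 2849 in the libraries labelled psp1.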

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

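Of the tests in this part, those of exchanged labels, of PSP1 at equal depth, of root tissue in aerial libraries, of the 3 explanations for the glucosinolate genes and of other splits of the libraries were chosen only after the results were seen. All directions are those of the genotype labels, and a difference of effects is given as roots minus aerial part on the log2 scale, called in the quasi-likelihood test over 12 libraries.

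PSP1 stood above WT in the aerial libraries labelled psp1 and differed from its effect in roots by -2.60. An exchange of the WT and psp1 labels in the aerial libraries alone would set genes called in both tissues against each other, provided that both tissues respond alike, yet 83.0% of 147 such genes moved the same way, against 48.3% by chance. Reads from a near copy are argued against by the 0 other loci that match the coding sequence of PSP1. After all aerial libraries were thinned to one depth, the log2 fold change of PSP1 was 2.29. Thinning keeps the expected share of each gene in a library. It could hardly move this value, so the test does not decide the part of depth. An exchange of labels in both tissues together was not tested. A biological source of PSP1 transcript in plants labelled psp1, such as an added copy of the gene or transcript from the mutated locus, may also account for the values and stays open, since no test of it was run. The titles of the libraries labelled psp1 begin with HS in both tissues, and the meaning of that prefix was not established here.

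The psp1-labelled aerial libraries varied more among themselves than the WT ones, with a biological coefficient of variation (from the common dispersion of edgeR) of 23.9% against 11.2%. WT libraries thinned to the same totals stayed at 11.2%, which is 46.9% of the psp1 value. This measure already leaves out counting error, so thinning could hardly move it and the test does not decide the part of depth. Root tissue in some psp1-labelled aerial libraries is argued against by summed root marker expression that differed by 1.09 times between the 3 libraries. That sum is mainly PYK10, which is also expressed in the WT aerial part, so a small share of root tissue could go unseen. Few starting molecules in these libraries remain a candidate explanation: the extra squared variation was 5.97 times as large among the genes with the lowest counts as among those with the highest, of 4 equal bins. Roots labelled psp1 gave a like ratio, 6.67, with a smaller extra spread. A true difference between plants labelled psp1 is open and was not tested.

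Aliphatic glucosinolate genes were lower in the aerial part and higher in roots of psp1-labelled plants, with an adjusted p of 4.46e-21 for the difference (0.00119 with an estimated correlation); in the aerial part alone 7 of 21 were called, 0 in the quasi-likelihood test, and the list had an adjusted p of 0.061 with an estimated correlation. Leaf tissue in the psp1-labelled roots would have lowered this list there, as its sum was 892.2 CPM in the WT aerial part and 2001 CPM in WT roots. The marker test, with leaf marker expression at 0.66 times that of WT roots, thus weighed an explanation that did not predict the rise. At equal depth the camera adjusted p of the difference was 1.26e-21. Thinning keeps the expected share of each gene and leaves in place whatever else went with the shallow libraries. That test therefore does not decide the part of lower depth. The uneven spread of psp1 aerial 2 and 3 as the whole cause is argued against by all 3 libraries: psp1 aerial 1, 2 and 3, each set against WT, gave medians of -0.86, -0.74 and -0.94 for this list, with 18, 18 and 19 of 21 members below 0. Open are a response of the tissues to the mutation in opposite directions, which rests on genotype labels that PSP1 in the aerial part leaves in doubt, and unequal growth stage or nutrient state of the plants, neither of which was tested.

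The remaining results stood out because the psp1 effect differed between tissues. In all, 315 genes did, and 170, 136 and 194 without WT aerial 1, 2 and 3. Of 39 other ways of splitting the libraries that were drawn, the 2 that kept the root libraries of a genotype together gave 166 and 272 genes. Those 2 mixed the genotypes in the aerial part and kept the root effect whole, which builds in a difference between tissues. The other 37 gave 0, and as they mix genotypes within a tissue they do not stand for an equal effect in both. Neither kind shows what an equal effect would give, so the splits cannot decide whether 315 genes could arise by chance. Among sulfur and methionine genes the differences were SULTR2;1 2.23, APR2 0.96, APR3 -1.18, MSRB5 -1.88 and MS2 1.75. Among glucosinolate genes they were BCAT4 2.69, CYP83A1 2.01, CYP79F2 2.26, IPMI1 3.25 and CYP79B3 -0.84. For nutrient genes they were GLN1;2 2.64, NRT1.1 1.82 and PHT1;4 2.17, and for primary metabolism GLYK -0.92, LHCB3 -0.88, BCA3 4.18, DIN10 -1.28 and THA1 -5.11. For defence and flavonoid genes they were VSP2 -1.92, FLS1 2.30, F3H 2.14 and CYP81D11 -2.72, and for other genes EMB1030 2.83, G3Pp1 2.77 and AT2G39980 3.41. TAT3 had a fitted difference of 12.49, which depends on the prior because a group without counts enters it. The calls of APR2, APR3, MSRB5, LHCB3, TAT3, GLYK, CYP79B3, VSP2, FLS1 and F3H were lost when at least 1 single library was left out, with adjusted p-values up to 0.031 and most losses (9) without WT aerial 2, and that of BCA3 at equal depth (0.0211).

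Among the lists, the adjusted p of the difference was 1.11e-06 for phosphate starvation (0.00322 with an estimated correlation), 7.4e-08 for carbon starvation (0.00322), 0.00019 for iron deficiency (0.04), 2.2e-06 for nitrogen assimilation (0.074), 8.24e-06 for the methionine cycle (0.0671), 0.0114 for sulfate transport (0.0671), and 0.00598 for both flavonoid synthesis (0.15) and photosynthesis (0.324).

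For comparisons of 3 against 3 libraries, 10 splits exist, too few for a share under 0.05, and in each the real split was the 1 with the largest value. The real split of the aerial part gave 387 genes and the highest other 9, that of roots 3172 and 1, that of tissues in WT 11729 and 2, and that of tissues in the libraries labelled psp1 8615 and 0. For lists the real split gave 10 and the highest other 4 in the aerial part, and 12 and 9 in roots. Every other split mixes genotypes, or tissues, within both groups. A true effect then adds to the spread and lowers the count, so the gap to the real split does not measure chance.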

How the results depend on the processing

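The thinned counts and the comparison of psp1 aerial 1 alone were chosen after the data were seen. In the aerial part the 387 calls became 792 at an adjusted p of 0.05, 193 with at least 2-fold change, 31 with the quasi-likelihood test, and between 112 and 710 without 1 library, while psp1 aerial 1 alone gave 944 with a spread taken from the WT libraries only, which assumes that it varies as they do; DESeq2, RLE, library totals, both other filters, a spread from all libraries, removal of organelle loci and thinning gave 270 to 523. In roots the 3172 calls became 1521 with at least 2-fold change and stayed within 1.5 times otherwise, apart from the block; both comparisons of tissues stayed within 1.5 times throughout. The interaction gave 936 at 0.05, 828 with DESeq2 and 136 to 374 without 1 library, against 315. With an estimated correlation the called lists went from 10 to 1 in the aerial part, from 12 to 6 in roots and from 9 to 4 for the interaction. Genes that rose in both tissues numbered 15 with the quasi-likelihood test and 161 at 0.05, and those that fell in both 1 and 108. A fit with a replicate block gave 21 genes in the aerial part, 1837 in roots and 281 for the interaction. That fit used the quasi-likelihood test, which without a block gave 31, 2232 and 315. The gap to the 387 and 3172 calls of the exact test is therefore in part one of test. Libraries of the same number deviated together weakly at most (r from -0.072 to 0.15). WT aerial part and WT roots of the same number had r of 0.027, 0.111 and 0.15, against -0.134 to 0.023 for other numbers, so a shared source stays open there. Stricter and looser thresholds move the counts by construction; for the other settings, including the rises to 710, 555 and 374 with 1 library fewer, the cause was not tested. Fry, planned as the additional list test, did not call photosynthesis (adjusted p = 0.141) or photorespiration (0.166) in the aerial part and called jasmonate (0.00298, down), heat shock (0.015, up) and the serine pathway (0.0256, up), which camera did not; it compares no list with other genes, and in roots it called all lists but the indolic (0.331) and heat shock (0.561). Of named calls, 11 of 33 in the aerial part, 61 of 63 in roots and 16 of 27 for the interaction were kept in every alternative, and none changed direction. Counts per transcript as deposited equal the main ones by construction, since each locus has 1 target, and were not run apart. At the depth of these libraries, simulated 2-fold changes were recovered in 46% of cases in the aerial part. They were given only to genes above a minimum mean count, and no other depth was simulated.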

Other observations

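The families and all tests of this part were chosen after the data were seen. Among gene families defined by annotated product, aquaporins were lower in the psp1-labelled aerial part, with 0 rises and 3 falls among 16, a median of -0.41 and an adjusted p of 3.64e-05 (0.261 with an estimated correlation). Resistance genes of the NBS-LRR class, which sense pathogens, had a median of 0.19 with 1 rise among 82 (adjusted p = 2.73e-05, and 0.32 with an estimated correlation). Glutathione S-transferases, which detoxify with glutathione, had 4 rises among 32 and a median of 0.25 (0.00442, and 0.136 with an estimated correlation). Heat shock proteins and chaperonins had 5 rises among 67 (0.00589, and 0.136 with an estimated correlation) and WRKY factors of defence 3 among 33 (0.0117, and 0.141 with an estimated correlation).

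In psp1-labelled roots, class III peroxidases had 21 rises and 5 falls among 56, with a median of 0.23 (adjusted p = 0.0184, and 0.222 with an estimated correlation). WRKY factors had 15 rises and 2 falls among 51, with a median of 0.40 (0.0184, and 0.222 with an estimated correlation), and NBS-LRR genes 21 and 8 among 98 (0.0433, and 0.556 with an estimated correlation). Histone genes, with 0 rises and 8 falls among 39 (0.0539), and cytochromes P450, with 30 and 17 among 155 (0.0806), were not called. No family of either tissue was called with an estimated correlation.

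Ribosomal protein genes of the nucleus were tested for a shared change in the psp1-labelled aerial part, because AT1G33120 encodes one. The test gave an adjusted p of 0.459, with 2 rises and 5 falls among 267, so no shared change was found. A block of linked loci around PSP1, as could follow from crossing, was tested in roots. Within 1 Mb of PSP1, 79 of 393 tested genes were called, 1.13 times the share elsewhere (Fisher's exact test p = 0.23). In the aerial part 7 of 368 were called, 0.78 times the share elsewhere (Fisher's exact test p = 0.609). No excess of calls near PSP1 was thus found. A block that changed few of its genes, or was far shorter than the window, would not show here and stays open.

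Summed leaf marker expression in roots was 1378 ± 45.1 CPM in WT and 903.3 ± 172 CPM in psp1-labelled libraries (SD, n = 3). Coding GC content and expression relative to the other WT libraries of the same tissue were related across genes most in psp1 aerial 1 (Spearman rho -0.255). For a library labelled psp1 this measure includes its difference from WT. Among genes with at least 50 counts predicted from the other libraries of the group, 0.27% in psp1 aerial 3 and 0.19% in psp1 roots 3 were more than 4 times above or below the prediction. In each WT library this was at most 0.02%. The main axes of a principal component analysis of all libraries held 82.5%, 4.9% and 3.3% of the variance, and psp1 aerial 3 lay at -84.5 on the last of these.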
